A study of Rattus norvegicus and Mus musculus with 18 samples.

How the data were processed

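CpG methylation was measured in brain cortex of 18 animals in 6 groups of 3. Per the labels, the rats were of the Sprague-Dawley strain and the mice of the C57BL/6J strain, and the cortex was flash frozen. In each species a healthy control group received vehicle, and animals exposed before birth to an injection (VPA in rats, poly I:C in mice) received vehicle or TAK-418. Groups and replicate numbers were taken from the labels. The labels number the libraries of a group as replicates, which were taken as separate animals. No litter, sex, age, dose or sequencing batch was given, so p-values measure the spread between these libraries. Cytosines of Y-chromosome sequences were listed in every animal, at 22290 to 26847 per rat and 5851 to 6540 per mouse. By this measure the groups did not differ in sex.

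Libraries were prepared by Active Motif, per the labels. The deposited values were a signed methylation fraction for each cytosine of a CpG, in tracks that name GBSA (a program that analyses bisulfite sequencing data), per the file headers. The genome builds were rn6 for rats and mm10 for mice, per the file headers and the submitters' processing notes. The absolute value was the methylation level and the sign marked the strand, as seen from the values. The aligner, the read minimum, the version of GBSA and the type of library were not given in the sources used here. The deposited fractions came without read counts or coverage, so the depth behind each level is unknown, and no binomial interval was computed. The number of cytosines listed was the nearest measure of depth, at 3839722 to 4094360 per rat and 3808867 to 4075475 per mouse. Positions are printed as the tracks give them. Whether they count from 0 or 1 was not given in the sources used here.

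Before the data were examined, a quasi-binomial or count test on reads with a minimum of 10 reads per CpG had been planned. Without read counts it was replaced. Cytosines listed in all 9 animals of a species were kept, which were 2970763 in rats (59.2% of those listed in any rat) and 3129367 in mice (65.2%). Cytosines of the same CpG on opposite strands were averaged, giving 2229251 autosomal CpGs in rats and 2341063 in mice. Over the CpGs with both strands listed, the levels of the strands correlated at 0.931 in rat control replicate 1 and 0.953 in mouse control replicate 1. These correlations are across CpGs, which are not independent, and were not computed in the other animals. Autosomal tiles of 1000 bp with at least 3 such CpGs were formed, and the level of a tile was the mean of its CpGs. There were 257682 tiles in rats and 253851 in mice.

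Mean levels per animal were compared between groups with two-sided exact permutation tests. With 3 animals against 3, the smallest p is 0.10, so no such test can reach 0.05. Benjamini-Hochberg adjustment covered 48 tests of global and tile class means, 72 tests of tiles grouped by level and 18 tests of the X, Y and mitochondrial sequences. Tiles and single CpGs were tested with limma 3.58.1 in R 4.3.3 on log2((level + 0.01) / (1 - level + 0.01)), written below as the log2 ratio. All 9 animals of a species entered the fit and the spread was tied to the mean level. A tile or CpG was called at a Benjamini-Hochberg adjusted p under 0.05. Means, permutations and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

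Tile tests were tested on simulated data with 200 changed tiles per comparison. The changed tiles were drawn only from tiles with a level between 20 and 80% before the change. Changes of 10 or 20 points were recovered in 0% of 40 tiles each in all 4 main comparisons. Changes of 40 points were recovered in 45% (VPA vehicle against control), 42.5% (VPA TAK-418 against VPA vehicle), 55% (poly I:C vehicle against control) and 70% (poly I:C TAK-418 against poly I:C vehicle). The same simulations gave 2, 5, 3 and 4 calls among unchanged tiles. All 200 changed tiles were present at once, and those recovered ease the Benjamini-Hochberg cutoff for every other tile. With few changed tiles the cutoff is stricter, so lower shares recovered and fewer such calls would be expected. No simulation without changed tiles was run. The shares recovered do not apply to tiles near the ends of the scale, where smaller differences were called. Between VPA vehicle and control rats, called tiles on chromosomes 7 and 12 differed by -3.27 and -2.84 points, with VPA rats at 0%.

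To ask whether TAK-418 effects ran opposite to model effects, the covariance over tiles of both effects was set beside that in simulated unchanged groups, because both effects share the vehicle-treated model animals. The simulated groups were drawn 20 times with a single spread per tile for the 3 groups. A version with a separate spread for each group was run after the first result had been seen, and is given as an alternative. So is a version that divided the vehicle-treated animals between the effects.

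Regions were named by a rule fixed before the data were examined, here applied to tiles: the 5 largest gains and 5 largest losses among called tiles whose groups did not overlap, and, where fewer than 5 tiles passed, the 5 with the smallest p. No annotation of the builds rn6 or mm10 was used, so regions are given by position without gene names. The planned promoter tests, the 22 gene lists and the comparison of promoters between rats and mice were not analysed here for that reason. Alternatives covered the weighting of CpGs, the offset, the scale, the spread, centring, tile size, CpG minimum, strand rule, sex chromosomes, a replicate block and leaving out each replicate.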

Results

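The data were CpG methylation levels of brain cortex from 9 rats and 9 mice. In each species 3 animals were healthy controls given vehicle, 3 were model animals given vehicle and 3 were model animals given TAK-418. Rat models had been exposed before birth to VPA (valproic acid, an antiepileptic drug that also inhibits histone deacetylases). Mouse models had been exposed before birth to poly I:C, a synthetic double-stranded RNA that sets off an antiviral immune response. TAK-418 inhibits the enzyme activity of LSD1 (KDM1A), which removes methyl groups from lysine 4 of histone H3. The series asked how DNA methylation differs between models and controls and between treated and vehicle-treated models.

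Cortex of both species had the bimodal methylation that is usual for mammalian tissue. In rats 12.3% of 1000 bp tiles were low (mean under 20%), 37.9% were intermediate (20 to 80%) and 49.8% were high (80% or more). In mice these shares were 13.2%, 31.0% and 55.7%. Tiles with 20 or more CpGs were mostly unmethylated, with 90.1% of them low in rats and 90.6% in mice. The levels of any 2 animals correlated at 0.947 to 0.959 in rats and 0.959 to 0.970 in mice, across tiles, which are not independent replicates. The median spread within groups (SD) in intermediate tiles was 7.02 points in rats and 6.54 points in mice.

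VPA-exposed rats were compared with control rats to ask what prenatal VPA leaves in cortical methylation. Global methylation of vehicle-treated VPA rats lay within the spread of the controls. The mean over autosomal CpGs was 51.5% ± 0.26 (SD, n = 3) in VPA rats and 51.7% ± 0.71 (SD, n = 3) in controls, a difference of -0.21 points (two-sided exact permutation p = 0.90). Intermediate tiles averaged 61.4% ± 0.64 and 62.0% ± 1.69 (exact permutation p = 0.70, n = 3 each), and tiles with 20 or more CpGs 8.18% ± 0.042 and 8.19% ± 0.13. The tile means of all 20 autosomes were lower in VPA rats, by -0.37 to -0.16 points, but control replicate 1, at 52.5%, carried much of this. Without that animal the global difference was 0.193 points, in the other direction. Over all cytosines listed in each animal it was -0.820 points.

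Of 257682 tiles, 4 passed the test between VPA vehicle and control rats (limma, Benjamini-Hochberg), 1 higher and 3 lower in VPA rats. The largest gain was on chromosome 12 at 36547000 to 36547999 (3 CpGs), where the level was 100% in all 3 VPA rats and 67.4% ± 12.2 (SD, n = 3) in controls, a log2 ratio difference of 5.58 ± 0.44 (SE, limma adjusted p = 0.0227). The largest loss was on chromosome 11 at 33471000 to 33471999 (3 CpGs), from 22.5% ± 10.1 in controls to 0% in all VPA rats (log2 ratio difference -4.84 ± 0.39). The other called tiles were nearly unmethylated in both groups: chromosome 7 at 12253000 to 12253999 (8 CpGs) had 3.27% ± 0.26 in controls and 0% in VPA rats, and chromosome 12 at 1000 to 1999 (3 CpGs) had 2.84% ± 0.35 and 0%. The tile with the next smallest p, on chromosome 2 at 144322000 to 144322999, was at 0% in controls and 2.52% ± 0.71 in VPA rats and did not pass (limma adjusted p = 0.14). In each called tile all 3 VPA rats were at exactly 0% or 100%. No tile passed on the untransformed level scale or with the replicate number as a block, where the count was 0 in both, and leaving out any single animal of these groups left 0 to 2 calls.

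TAK-418-treated and vehicle-treated VPA rats were compared to ask what the inhibitor changed in the model. Mean methylation was 51.4% ± 0.94 (SD, n = 3) with TAK-418 against 51.5% ± 0.26 with vehicle, a difference of -0.14 points (exact permutation p = 1.0). TAK-418 replicate 2, at 50.3%, stood below the other animals. Without that animal the difference was 0.402 points in the other direction. Over all cytosines listed the difference was 0.217 points. Against controls the treated rats differed by -0.35 points (exact permutation p = 0.70), and by 0.193 points without TAK-418 replicate 2 or 0.050 points without control replicate 1. Tiles with a mean under 2% averaged 0.633% ± 0.011 in vehicle-treated VPA rats, above each TAK-418-treated rat (0.587% ± 0.0057) and each control (0.606% ± 0.021), with an exact permutation p of 0.10 in both comparisons (n = 3 each) and adjusted p = 0.33 over 72 tests. Mitochondrial CpGs, also nearly unmethylated, averaged 2.64% ± 0.56 in vehicle-treated VPA rats, 1.54% ± 0.57 with TAK-418 and 1.48% ± 0.84 in controls (exact permutation p = 0.20 for each comparison with vehicle, n = 3 each, adjusted p = 0.90 over 18 tests). Incomplete bisulfite conversion, which would raise unmethylated CpGs most, was not tested for these differences in rats.

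No tile passed between TAK-418 and vehicle in VPA rats (limma, Benjamini-Hochberg, 0 calls), and 12160 tiles (4.72%) had an unadjusted p under 0.05. Without VPA vehicle replicate 2 there was 1 call, and without VPA vehicle replicate 3 or TAK-418 replicate 3 there were 2. The smallest p values were in the tiles of chromosomes 12 and 11 named above. The chromosome 12 tile had 74.7% ± 4.11 (SD, n = 3) with TAK-418 against 100% with vehicle (limma adjusted p = 0.123), and the chromosome 11 tile 14.2% ± 4.24 against 0% (limma adjusted p = 0.151). Both treated means lay between those of vehicle-treated VPA rats and controls. On chromosome 2 at 32102000 to 32102999 (4 CpGs) the level was 4.83% ± 0.84 with vehicle, 22.0% ± 3.10 with TAK-418 and 24.7% ± 6.19 in controls (limma adjusted p = 0.798). The remaining tiles, on chromosome 2 at 144322000 to 144322999 and chromosome 3 at 111013000 to 111013999, were at 0% with TAK-418 and at 2.52% ± 0.71 and 1.80% ± 0.19 with vehicle. Because these tiles were picked for extreme vehicle values, a treated mean nearer to controls also arises by chance. Between TAK-418-treated VPA rats and controls 1 tile passed, the one on chromosome 7 (limma adjusted p = 0.0468), at 0% in all treated rats. The next was chromosome 12 at 1000 to 1999, at 0% in both VPA groups. On chromosome 17 at 78347000 to 78347999 controls had 100%, vehicle 84.1% ± 3.61 and TAK-418 74.1% ± 12.8. On chromosome 9 at 73205000 to 73205999 these were 0%, 2.78% ± 0.56 and 2.78% ± 1.05. On chromosome 12 at 8726000 to 8726999 they were 1.16% ± 0.39, 2.73% ± 0.64 and 6.09% ± 0.57.

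Every vehicle-treated poly I:C mouse had a higher mean cortical methylation than every control mouse. The mean over autosomal CpGs was 49.6% ± 0.32 (SD, n = 3) in vehicle-treated poly I:C mice and 48.7% ± 0.15 (SD, n = 3) in controls, a difference of 0.84 points. The difference was largest in intermediate tiles, at 60.8% ± 1.05 against 58.1% ± 0.63, or 2.70 points. It was 3.72 points in tiles with a mean of 30 to 40% and -0.0056 points in tiles under 2%. Tiles with 20 or more CpGs differed by 0.16 points and high tiles by 0.48 points. The tile means of all 19 autosomes were higher in poly I:C mice, by 0.976 to 1.27 points. The two-sided exact permutation p was 0.10 for the global, low, intermediate and high means (n = 3 each), the smallest that 3 against 3 allows, with adjusted p = 0.28 over 48 tests. The labels do not give litters or batches, so exposure cannot be separated from other differences between the control and model animals.

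**Figure D1:**
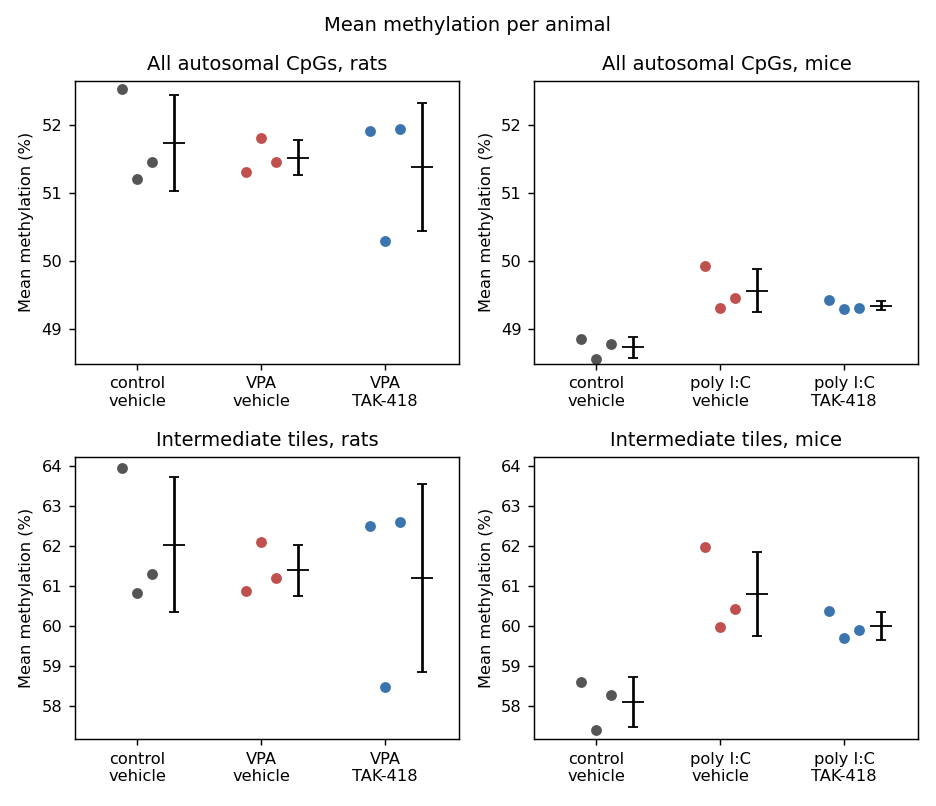
Mean methylation (%) of each animal over all autosomal CpGs (top) and over intermediate tiles with a mean of 20 to 80% (bottom), in rats (left) and mice (right); points are animals, and the bar beside them is the group mean with SD (n = 3). The 3 control mice lie below all 6 poly I:C mice in both measures, the rat groups overlap, and the vertical axes do not start at 0.

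**Figure D2:**
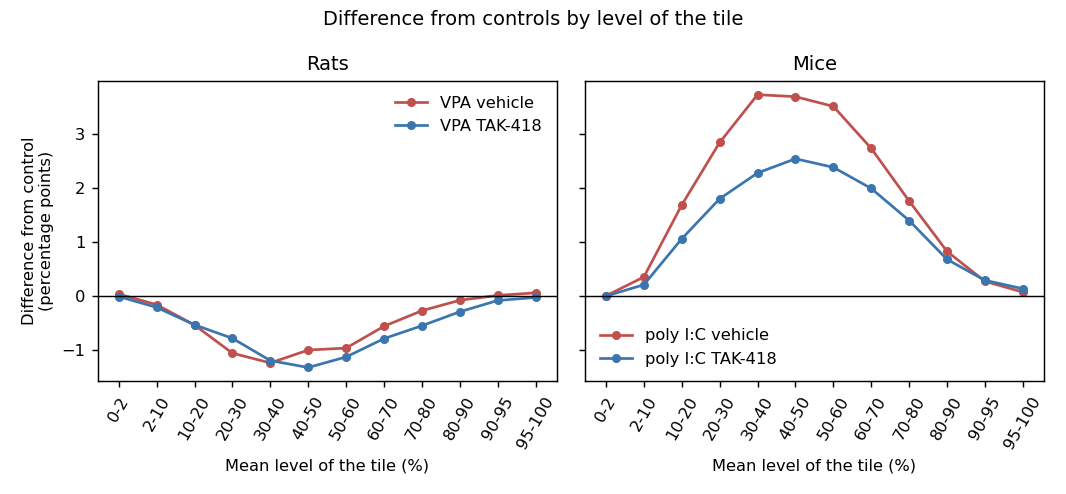
Difference from controls in mean methylation (percentage points) for tiles grouped by their mean level over the 9 animals of a species (%), for vehicle-treated and TAK-418-treated models. In mice vehicle-treated animals differ most at 30 to 40%, by 3.72 points, and by -0.0056 points under 2%, and the rat differences lie between -1.33 and 0.050 points.

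The difference in mice was spread over many tiles and none passed singly. Between vehicle-treated poly I:C mice and controls 0 of 253851 tiles passed (limma, Benjamini-Hochberg), and 2 passed without vehicle replicate 2. At an unadjusted p under 0.05 there were 15464 tiles (6.09%), 11078 higher and 4386 lower in poly I:C mice. With each animal centred on its mean over tiles these were 7504 and 6667. Groups did not overlap in 29743 tiles (11.7%, against 10% by chance).

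Among the 5 tiles with the smallest p, the largest difference was on chromosome 16 at 93456000 to 93456999 (5 CpGs), with 23.4% ± 3.99 (SD, n = 3) in controls, 63.0% ± 3.44 in vehicle-treated and 54.8% ± 2.46 in TAK-418-treated poly I:C mice. The difference of vehicle-treated mice from controls was 39.5 points (log2 ratio difference 2.43 ± 0.25, SE, limma adjusted p = 0.313). It came from the CpGs at 93456762, 93456770 and 93456782. Controls had 0 to 14.3% at these CpGs, and all 6 poly I:C mice had 50 to 77.8%. These CpGs lie close together and may be covered by the same reads, so they are not independent measurements. At 93456895 and 93456958 the control means were 49.0% and 58.7% and the vehicle-treated means 54.6% and 59.6%. The TAK-418-treated means there were 35.2% (animals at 50, 37.5 and 18.2%) and 67.9%. The lower tile mean of treated than of vehicle-treated mice thus also reflects the CpG at 93456895. The tiles on chromosome 7 at 55298000 to 55298999 and chromosome 11 at 27429000 to 27429999 were at 100% in vehicle-treated poly I:C mice, against 86.2% ± 3.18 and 83.3% ± 5.56 in controls (limma adjusted p = 0.313 and 0.394). The tiles on chromosome 5 at 123750000 to 123750999 and chromosome 14 at 73324000 to 73324999 lay under 2% in both groups.

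**Figure D3:**
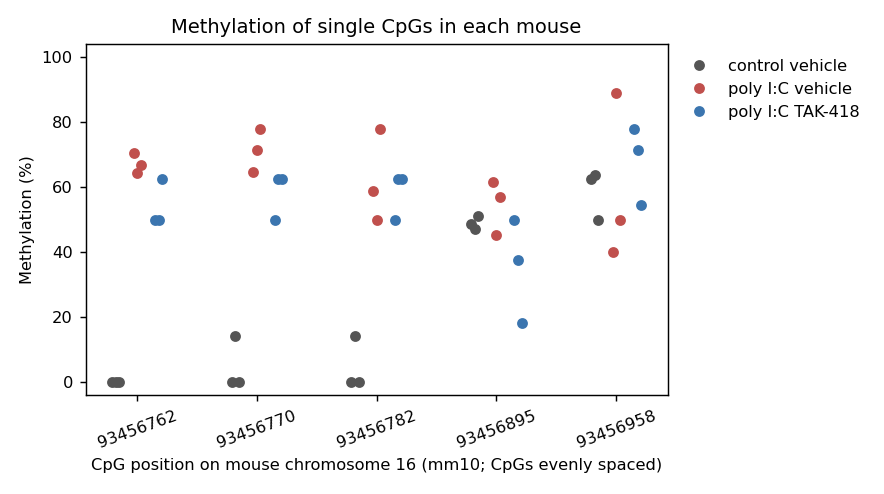
Methylation (%) of the 5 CpGs of the chromosome 16 tile in each mouse, by position in mm10, with the CpGs evenly spaced; points are animals. At the first 3 CpGs the controls lie at 0 to 14.3% and the 6 poly I:C mice at 50 to 77.8%, and at the other 2 the groups overlap.

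TAK-418 treatment of poly I:C mice was followed by a mean of 49.3% ± 0.070 (SD, n = 3), which was -0.22 points from vehicle-treated poly I:C mice (exact permutation p = 0.20). Intermediate tiles of the 3 treated mice lay between 59.7% and 60.4% (SD 0.35), on average -0.79 points from vehicle (exact permutation p = 0.20). Tiles with 20 or more CpGs did not overlap between these groups, at 7.77% ± 0.019 with TAK-418 and 7.84% ± 0.067 with vehicle, a difference of -0.070 points (exact permutation p = 0.10, n = 3 each, adjusted p = 0.28 over 48 tests). Vehicle replicate 1, at 49.9%, was the highest mouse, and without it the differences were -0.0411 points globally, -0.204 in intermediate tiles and -0.0310 in tiles with 20 or more CpGs. Treated mice stayed above controls, by 0.62 points globally and 1.90 points in intermediate tiles, with no overlap (exact permutation p = 0.10 each, n = 3, adjusted p = 0.28).

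Of 253851 tiles 1 passed between TAK-418 and vehicle in poly I:C mice (limma, Benjamini-Hochberg). It lay on chromosome 12 at 111417000 to 111417999 (3 CpGs), with 17.0% ± 3.97 (SD, n = 3) with vehicle, 0% in all 3 treated mice and 6.61% ± 2.55 in controls (log2 ratio difference -4.41 ± 0.28, SE, limma adjusted p = 0.00998). The call was lost on the level scale (limma adjusted p = 0.457), with the replicate block and without vehicle replicate 1 or TAK-418 replicate 3 (0 calls in each). Without vehicle replicate 2 there were 2 calls, and without TAK-418 replicate 2 there were 5. With the spread not tied to the mean level there were 17. The next tiles did not pass. On chromosome 1 at 159407000 to 159407999 the level was 100% with vehicle, 76.9% ± 1.60 with TAK-418 and 82.9% ± 9.16 in controls (limma adjusted p = 0.189). On chromosome 7 at 55298000 to 55298999 it was 100%, 87.2% ± 2.81 and 86.2% ± 3.18. On chromosome 18 at 69331000 to 69331999 it was 83.9% ± 4.81, 100% and 87.0% ± 5.78, and at 32376000 to 32376999 it was 0%, 1.85% ± 0.33 and 0%. Between treated mice and controls 0 tiles passed (limma, smallest adjusted p = 0.213), and 14546 had an unadjusted p under 0.05. The smallest p values were in the chromosome 12 tile, the chromosome 18 tile at 32376000 and the following tiles. On chromosome 18 at 56736000 to 56736999 controls had 78.5% ± 5.59, vehicle 90.9% ± 4.81 and TAK-418 100%. On chromosome 13 at 104140000 to 104140999 these were 85.3% ± 4.02, 92.0% ± 1.57 and 100%. On chromosome 14 at 7942000 to 7942999 they were 83.8% ± 1.65, 88.1% ± 3.21 and 99.6% ± 0.64.

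Single CpGs passed in much larger numbers than tiles. In rats 3848 of 2229251 CpGs passed between VPA vehicle and control, 3779 between TAK-418 and VPA vehicle and 3298 between TAK-418 and control (limma, Benjamini-Hochberg). In mice 4955 of 2341063 passed between poly I:C vehicle and control, 4432 between TAK-418 and poly I:C vehicle and 4813 between TAK-418 and control. Of all these calls 99.3% had a group with all 3 animals at exactly 0% or 100%, as had 33.01 to 37.51% of the CpGs tested in each comparison. On the untransformed level scale 248 and 338 passed in the first and second rat comparisons, and 963 and 551 in the first and second mouse comparisons. With the replicate block the counts were 259, 399, 1134 and 602 in the same order.

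Whether treated models lay nearer to controls was asked over all tiles. In rats the effects of VPA and of TAK-418 had a correlation of -0.51 (-0.50 in simulated unchanged groups) and a covariance of -13.4 (-13.4 simulated), a difference of 0.020. With at least 5 CpGs per tile and in intermediate tiles the rat covariance was above the simulated range, at -8.31 (range -8.78 to -8.41) and -22.504 (range -23.221 to -22.524). In mice the correlation was -0.49 (-0.50 simulated) and the covariance -11.6 (-10.8 simulated), a difference of -0.74, below the range of -11.0 to -10.7 of the 20 simulations. With the 3 vehicle-treated animals divided between the effects, so that no library was shared, the covariance averaged -1.10 in mice (-2.20 to -0.241 over 6 divisions) and -0.082 in rats (-0.302 to 0.179). In mice it was -2.20 with vehicle replicate 1 alone in the TAK-418 effect and -0.241 with vehicle replicate 2 alone there. The shift of mean levels in mice, which differed with the level of the tile, also enters this covariance. The divisions reuse the same animals and are not independent, and no test was made of them. The range of the simulations does not cover variation between animals that runs across many tiles.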

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

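The tests of incomplete conversion, of depth and of levels at 0% or 100% and the counts over other splits were chosen only after the results were seen.

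The effect of the model on intermediate tiles differed between species by 3.33 points, at 2.70 points in mice and -0.64 points in rats (exact permutation of labels within each species, 400 permutations, p = 0.035, adjusted p = 0.17 over 8 tests). It did not hold after adjustment. Species, strain and exposure differ together, so they cannot be separated. X-chromosome CpGs, outside the main measurement, averaged 52.84% in vehicle-treated and 52.69% in TAK-418-treated poly I:C mice, with every animal above every control (mean 52.3%, exact permutation p = 0.10 each, n = 3, adjusted p = 0.90 over 18 tests).

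For the higher methylation of poly I:C mice, incomplete bisulfite conversion would raise unmethylated tiles most, yet tiles under 2% differed by -0.0083 points between the 6 poly I:C mice and the 3 controls, against 3.11 points in tiles of 40 to 50%. Depth, as the number of cytosines listed, was greater in the control in 11 of 18 pairs of a control and a poly I:C mouse, so the groups were not parted by it. Tissue make-up, such as a different mix of cell types in the dissected cortex, was a further candidate. The difference of vehicle replicates 1 and 2 correlated with the difference of TAK-418 from control at 0.0327 over 20982 tiles. This lies between the bounds of 0.05 and 0.02 set beforehand, so it did not decide. Any shift that runs across many tiles of an animal could give such a correlation, and no cell type marker was examined. Replicates 1 and 3 gave 0.0327 and replicates 2 and 3 gave -0.0010, so the correlation appeared only in pairs with replicate 1, the mouse with the highest mean. In rats, for which no bound had been set, control replicate 1 minus 2 correlated with TAK-418 replicate 3 minus 2 at 0.0909 over 24483 tiles. In both groups these were the animals with the highest and the lowest global mean, and other rat differences were not correlated in this way. Both rat differences lie within a group, so such shared variation also occurred without a difference in exposure. The prenatal exposure, litter, sequencing batch and tissue make-up stay open and cannot be told apart.

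The large number of single CpGs called may come from levels at the ends of the scale: 99.3% of 25125 calls had a group with all 3 animals at exactly 0% or 100%, against 33.01 to 37.51% of the CpGs tested, where the observed spread of the group is 0. The numbers of calls in other splits of the same animals were similar. Of 10 splits per comparison, the number with as many CpG calls as the real one, itself included, was 4 (3848 real, highest other 4435), 9 (3779, 4352) and 9 (3298, 5297) in rats. In mice it was 1 (4955, 4763), 3 (4432, 4511) and 2 (4813, 4822). The order is model vehicle against control, TAK-418 against model vehicle and TAK-418 against control.

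For tiles in the same order, the number of splits with as many calls was 1 (4 real, highest other 3), 10 (0, 2) and 3 (1, 2) in rats, and 10 (0, 3), 7 (1, 2) and 10 (0, 3) in mice. With 10 splits a share under 0.05 cannot be reached. At an unadjusted p under 0.05 the real split of vehicle-treated poly I:C and control mice had 15464 tiles and the highest other split 12563. In rats another split of TAK-418-treated and control animals had 15688 tiles against 11371 in the real one.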

How the results depend on the processing

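All alternatives were chosen after seeing the data, except the replicate block, only the 6 animals compared, the 10-point minimum, sex chromosomes, 500 bp tiles for counts of called tiles, and leaving out replicates for those counts and for the global means of the 4 main comparisons. Alternatives that need read counts (read minimums, coverage, edgeR, Fisher's test), promoters and gene lists were not run, nor was the reversal over called tiles. The depth behind the levels is unknown. The cause of each change below was not tested.

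The mouse shift kept its direction in every alternative run. The global difference of vehicle-treated poly I:C mice was 1.15 points with equal weight per tile (0.658 to 0.964 leaving out each replicate), and that of TAK-418 from control 0.861 (0.532 to 0.678). In intermediate tiles leaving out replicates gave 2.11 to 3.11. Leaving out replicates, TAK-418 minus poly I:C vehicle ranged from -0.347 to -0.0411 globally and -1.20 to -0.204 in intermediate tiles. In tiles with 20 or more CpGs it then ranged from -0.0908 to -0.0310. Over all cytosines listed the global difference was -0.399. The rat differences changed sign when single replicates were left out, TAK-418 minus control among them (-0.634 to 0.193). VPA vehicle minus control was -0.820 over all cytosines listed, with -0.472 to 0.193 leaving out replicates (-1.24 to 0.328 in intermediate tiles). TAK-418 minus VPA vehicle was 0.217 over all cytosines listed, reversed, with -0.425 to 0.402 leaving out replicates (-0.903 to 1.15 in intermediate tiles).

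Called tiles between VPA vehicle and control numbered 0 with the replicate block, the level scale, an offset of 0.05, at least 10 CpGs or either strand, 1 with only the 6 animals compared or at least 5 CpGs, 2 with a difference of at least 10 points, and 0 to 2 leaving out replicates. Between TAK-418 and VPA vehicle they numbered 2 with an offset of 0.001 or centring, and 0 to 2 leaving out replicates. Between poly I:C vehicle and control they numbered 2 with the spread not tied to the mean level, and 0 to 2 leaving out replicates. Between TAK-418 and poly I:C vehicle they numbered 0 with the replicate block, the level scale, an offset of 0.05, only the 6 animals compared, at least 5 or at least 10 CpGs, 3 with 500 bp tiles, 17 with the spread not tied to the mean level, and 0 to 5 leaving out replicates. Minimums of 5 and 10 CpGs left untested the called mouse tile (3 CpGs) and, in rats, 3 and 4 of the 4 called tiles. The other 33 tile alternatives stayed within 1.5 times the main count.

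Called CpGs fell to 248, 338, 963 and 551 on the level scale and to 259, 399, 1134 and 602 with the replicate block, in the same order of comparisons. Same-numbered animals of different groups had correlations of their deviations of -0.036 to 0.049 in rats and -0.0028 to 0.022 in mice, against -0.087 to 0.051 and -0.028 to 0.0074 for different numbers. All were under 0.1, and the numbers were not taken to pair the animals. Such low values cannot exclude pairing, because the spread of single tiles is large beside a shift of a whole animal. In all 3 mouse groups replicate 1 had the highest and replicate 2 the lowest global and intermediate mean.

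The covariance difference of the reversal was 0.262 with at least 5 CpGs, 0.400 in intermediate tiles and, reversed, -0.0813 with a spread for each group and -0.0821 with the vehicle animals divided between the effects in rats, the first and second outside the simulated range. In mice it was -1.34 in intermediate tiles, -0.698 with at least 5 CpGs, -1.01 with a spread for each group and -1.10 with the vehicle animals divided.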

Other observations

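The comparison of controls with all poly I:C mice and the counts of tiles in which 3 animals stood apart were chosen only after the results were seen. The bounds for the lone CpGs were written before their ratio was computed.

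All 6 poly I:C mice together had a global mean of 49.5% ± 0.24 (SD, n = 6) against 48.7% ± 0.15 in the 3 controls, a difference of 0.73 points. Intermediate tiles differed by 2.30 points, high tiles by 0.46 and X-chromosome CpGs by 0.44. In rats the same comparison gave -0.28 points. No p is given, because the animals were pooled after the controls had been seen to lie below both poly I:C groups.

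Tiles in which 3 animals lay at least 20 points from the other 6 were rare. There were 2 such tiles for the control mice, 2 for vehicle-treated and 0 for TAK-418-treated poly I:C mice, and 0 to 3 for the 81 mixed sets of 3 mice. In rats the groups had 0, 1 and 0, and mixed sets 0 to 4.

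Mitochondrial CpGs of mice averaged 1.74% ± 0.10 in controls, 1.67% ± 0.22 in vehicle-treated and 1.75% ± 0.11 in TAK-418-treated poly I:C mice (SD, n = 3 each).

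CpGs that differed by at least 80 points between 2 animals, while the mean of their neighbours within 50 bp differed by under 20, numbered 2271 in rats and 1506 in mice. Sequence variants of outbred Sprague-Dawley rats were a candidate explanation. Per CpG that had such neighbours, the ratio of rats to mice was 1.64, below the value of 3 set for that explanation and above the 1.5 set against it. The remaining CpGs that differed by at least 80 points, whose neighbours differed by 20 points or more, had a ratio of 1.60. The excess was thus not special to lone CpGs. These remaining CpGs may also hold sequence variants, so the explanation stays open.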
